A study of Oreochromis niloticus with 6 samples.

How the data were processed

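Small RNA was sequenced from gill tissue of genetically improved farmed tilapia (Oreochromis niloticus), a fast-growing selected line, in 6 libraries. Per the labels, 3 libraries came from a control group kept at normal oxygen and 3 from an acute hypoxia group, in which nitrogen was used to lower dissolved oxygen to 1.02 mg/L, and both were sampled at 96 h. Per the labels' protocols, RNA of 15 to 50 nt was excised from a gel, libraries were made with an Illumina small RNA kit and read single-end on an Illumina HiSeq instrument. The descriptions differ on numbers: one gives 90 fish in 6 tanks with 15 per tank, the other 4 replicates per group and 30 fish per tank. The description with 30 fish per tank has 4 fish sampled per tank. Whether a library holds 1 fish or a pool is not stated, so p-values measure the spread between these libraries, which may be partly technical. The tank of each library is not stated either. If the libraries of a group shared a tank, a difference between tanks could not be told from one of oxygen.

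The table has 1143 rows with a sequence, each a mature or predicted miRNA sequence with its name, class and precursor location. A further 13 lines were not used here. Per the file headers, the authors grouped rows by how the reads matched known precursors and the genome; the aligner, the miRBase release and the genome build are not given in the sources used here. The authors deposited read numbers that need not be whole, and their unit was taken to be expected counts: 72.4% of values were whole within 0.001. All 6 values were whole in 75.47% of sequences standing in 1 row and in 4.62% of those in 2 rows, and 90.77% of the latter became whole when doubled, as when reads are divided between rows with one sequence. The authors also deposited normalized values, used here as a signal, which equal the expected counts times 1 factor per library between 0.7432 and 1.6205; how the factors were set is not given in the sources used here.

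The feature was the distinct mature sequence. Of 897 distinct sequences, 714 carried a miRNA name and 183 were predicted; 212 stood in more than 1 row with equal values, and the value of 1 row was used. Expected counts were rounded to whole numbers. Counts were also summed over all rows whose names share a miRNA number and arm, which gave 349 families; these sums add divided reads together again, and their library sizes were the row totals. Row totals ranged from 5262943 to 11025204 reads. Totals with 1 row per sequence ranged from 3376123 to 7502687, at which 3 counts correspond to 0.4 to 0.889 CPM (counts scaled to a common library size). Chi-square values per degree of freedom between libraries of a group were 159 to 922, above counting noise, so no pair was treated as 1 library in 2 copies; this does not show that the libraries are separate fish.

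Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood F test of hypoxia against control with no other covariate, and Benjamini-Hochberg adjustment over all features tested, called at adjusted p under 0.05. Standard errors (SE) of log2 fold changes were obtained as the absolute fold change divided by the root of F. CPM values are TMM-normalized means ± SD over 3 libraries. The biological coefficient of variation was 0.387 for sequences and 0.351 for families. Sets of families were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it. The 15 lists were hypoxia-induced, HIF-targeting, erythroid, leukocyte, epithelial, skeletal muscle, vascular, cartilage and mesenchyme, neural, sensory epithelium, liver, let-7, miR-17-92 clusters, Hox clusters and miR-34; liver had 1 tested family, so 14 were tested. Shares of counts and count-weighted length were compared with exact two-sided permutation tests (scipy 1.17.1), whose smallest p for 3 against 3 is 0.1.

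Sequences were named by a rule: those past the threshold, or, where fewer than 5 passed in a direction, the 5 with the smallest p; the 10 most abundant; the 3 most abundant families of each list and every family that passed; and the 2 predicted sequences with the smallest p in each direction. The design, the lists, this rule and most alternatives were fixed before the data were examined. Alternatives were RLE, upper quartile and no scaling, no count filter, a mean CPM of at least 10, a block on the replicate number, each library left out, removal of the 10 most abundant sequences, DESeq2 1.42.0, limma-voom, limma on the normalized values with pseudocounts of 1 and 10, rows as deposited, family letters kept apart, and a threshold of 0.1 or an unadjusted p. Chosen after seeing the data were reads summed over rows (also for shares and length), the authors' factors, the more abundant arm alone, a per-library correction for GC content by loess, and removal of sequences unmatched to the genome. No sequence of that unmatched class is printed.

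The steps were tested on simulated data. For sequences, with 200 of 623 changed, 25% of 2-fold and 79% of 4-fold changes were recovered with 1 false call; for families, with 60 of 275 changed, 40% and 73.3%, also with 1 false call. A simulated set of changed families was recovered by camera at an adjusted p of 0.000111, whereas a set of changed sequences was not, at 0.507, and lists were tested on families alone. In the data, the hypoxia-induced list had an estimated correlation of 0.306, against the preset 0.01. A grouping of the libraries other than by oxygen gave 53 called sequences. Whether the simulated rates hold with such structure was not tested. In 623 simulated sequences with a GC trend and no group effect, the GC correction reduced 46 calls to 0. That simulation had less variation between libraries than the data, and its groups were set by the direction of a linear GC trend. The real control and hypoxia groups each hold both directions, so it does not show how the correction performs on them.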

Results

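Small RNA libraries from gills of 3 control and 3 hypoxia samples of farmed tilapia, taken at 96 h, were compared. The gill is the organ of oxygen uptake in fish, and the comparison addresses which miRNAs differ when water oxygen is low. Reads per library summed to 11025204, 5262943 and 10523441 over the rows of the table in control replicates 1 to 3, and to 9829053, 10953687 and 7610794 in hypoxia replicates 1 to 3. Named miRNAs took 99.76% ± 0.0088 of counts in control and 99.77% ± 0.0351 in hypoxia (SD, n = 3 each; exact permutation p = 0.8, two-sided). With the value of 1 row per sequence, the 10 most abundant sequences took 48.3% ± 2.0 in control and 50.9% ± 2.58 in hypoxia (SD, n = 3 each; exact permutation p = 0.2, where 0.1 is the smallest possible). With reads summed over rows, 7 of the 10 stayed among them and the share was 53.3% ± 2.91 and 53.8% ± 2.05 (SD, n = 3 each; exact permutation p = 1.0). The count-weighted length was 22.41 ± 0.0287 nt and 22.42 ± 0.0231 nt (SD, n = 3 each; exact permutation p = 0.7).

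Hypoxia gills held more miR-147 and more miR-210. Both arms of miR-147, a miRNA known in mammals from Toll-like receptor responses of macrophages, rose about as much as each other: the 5p family from 2.46 ± 0.526 to 27.8 ± 3.27 CPM and the 3p family from 6.52 ± 2.6 to 78.7 ± 18.6 CPM (SD, n = 3 each). The 3p family of miR-210, the miRNA most regularly induced by hypoxia in mammalian cells, rose from 616 ± 107 to 2420 ± 633 CPM (SD, n = 3 each). In all 3 families each hypoxia library lay above each control library. No miRNA fell by the same test.

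**Figure D1:**
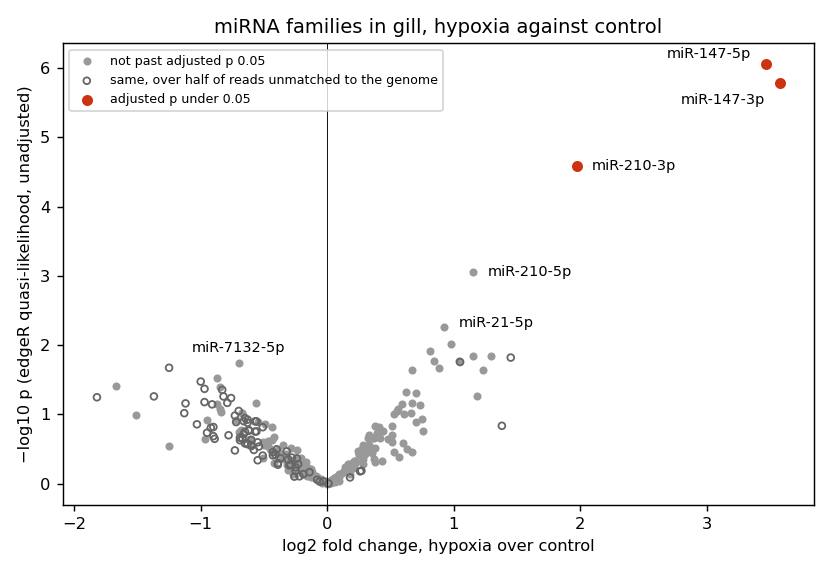
Each point is 1 of 275 miRNA families, with the log2 fold change of hypoxia over control on the x axis and −log10 of the unadjusted edgeR p on the y axis; filled red points passed an adjusted p of 0.05, and open circles are families with over 50% of reads unmatched to the genome. The families miR-147-5p (3.47), miR-147-3p (3.58) and miR-210-3p (1.97) stand apart on the right.

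In log2 units the families changed by 3.47 (SE 0.37, edgeR adjusted p = 0.000221) for miR-147-5p, 3.58 (SE 0.4, adjusted p = 0.000221) for miR-147-3p and 1.97 (SE 0.29, adjusted p = 0.00238) for miR-210-3p. These were 3 of 275 families tested, all higher. The other arm, miR-210-5p, was at 535 ± 36.9 CPM in control and 1190 ± 194 CPM in hypoxia (SD, n = 3 each) and did not pass (log2 fold change 1.15, SE 0.26, edgeR adjusted p = 0.0607). Without control replicate 1, miR-210-3p no longer passed (edgeR adjusted p = 0.0626; range over all alternatives 9.07e-09 to 0.0626), at a log2 fold change of 1.95 (1.76 to 2.27 over all alternatives). Without hypoxia replicate 3 the number of families past the threshold was 22, of which 16 were higher and 6 lower, and it included the 3 above.

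At the level of single sequences, 3 of 623 rose and 0 fell in the edgeR test. The sequence hhi-mir-147b-p5_1ss9CG (ACAGAATCGTTTCTGCACAAACT) rose by 3.40 in log2 units (SE 0.32, edgeR adjusted p = 0.00177) and hhi-miR-147b_R-1_1ss12CT (GTGTGCGGAAATGCTTCTGCTC) by 3.50 (SE 0.39, adjusted p = 0.00308). Both came from 1 precursor, placed by the authors on the minus strand of scaffold GL831355.1 from 901472 to 901564, in a build that is not named. The miR-147b 5p sequence was counted 30, 11 and 32 times in control and 241, 300 and 198 times in hypoxia, so its control level rests on few reads. The sequence ssa-miR-210-3p_R+2 (CTGTGCGTGTGACAGCGGCTAA), from the minus strand of scaffold GL831142.1 between 841878 and 841974, rose by 1.90 (SE 0.27, edgeR adjusted p = 0.0151). Gene annotation around these precursors was not used here. The count of sequences past the threshold was 14, all higher, without hypoxia replicate 3 and 5, 4 higher and 1 lower, without control replicate 2. The lower one (edgeR adjusted p = 0.00674), also called with no count filter (adjusted p = 0.0407), is the predicted sequence PC-3p-4870_360, named here after its values were seen. It was counted 220, 0 and 184 times in control and 0 times in each hypoxia library, and the count filter left it out of the main test. The miR-210 sequence did not pass without control replicate 1, 2 or 3 or without hypoxia replicate 1, with edgeR adjusted p from 0.0624 to 0.114 in these and from 4.02e-08 to 0.114 over all alternatives, at log2 fold changes of 1.74 to 2.08.

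Further miR-210 sequences did not pass: xtr-miR-210_1ss22AC had a log2 fold change of 1.76 (edgeR adjusted p = 0.08) and ssa-miR-210-5p_1ss16TC of 1.07 (adjusted p = 0.107); they passed in 5 and 3 of 21 alternatives. The predicted sequence PC-3p-3211_637 begins with the whole 3p sequence of miR-147b and maps to the same scaffold from 901468 to 901563; it went from 4.64 ± 3.06 to 32.5 ± 4.13 CPM (SD, n = 3 each) and did not pass in the main test (log2 fold change 2.77, edgeR adjusted p = 0.062). It passed in 14 of 21 alternatives, among them RLE scaling (edgeR adjusted p = 0.0257), DESeq2 (1.73e-07) and limma-voom (0.0293), in a range of 1.73e-07 to 0.239. A second predicted sequence, PC-3p-11134_116, was at 1.34 ± 0.0605 and 5.56 ± 0.969 CPM (SD, n = 3 each; edgeR adjusted p = 0.107).

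Toward lower values in hypoxia, none of the 5 sequences with the smallest p passed. ssa-miR-7132a-5p_1ss10AC was at 1410 ± 153 CPM in control and 737 ± 125 CPM in hypoxia, and ssa-miR-7132b-5p at 6540 ± 1080 and 3780 ± 763 CPM (SD, n = 3 each; edgeR adjusted p = 0.21 and 0.345). For ssa-let-7e-3p_1ss22CT, ssa-miR-338a-4-5p and ssa-miR-130b-3p_R+1 the log2 fold changes were -1.75, -1.51 and -2.06, with edgeR adjusted p of 0.301, 0.367 and 0.395. The predicted sequences PC-3p-16373_69 and PC-3p-5453_308 had log2 fold changes of -1.89 and -2.49 (edgeR adjusted p = 0.442 and 0.471), and the latter rests on control replicate 2 with 129 CPM against at most 11.9 CPM elsewhere. At an unadjusted edgeR p under 0.05 there were 62 sequences, 39 higher and 23 lower, against 31 by chance; DESeq2 called 10, all higher, and limma-voom 4. The groups did not overlap for 79 sequences or 12.7%, where chance gives 10%.

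The 10 sequences most abundant by the value of 1 row did not pass the test. ssa-miR-150-5p_R+2_1ss1TA, of a family enriched in mature lymphocytes, was at 75800 ± 12600 CPM in control and 87400 ± 21200 CPM in hypoxia (SD, n = 3 each). ssa-miR-21b-5p was at 53600 ± 14600 and 97600 ± 16000 CPM (SD, n = 3 each), with each hypoxia library above each control library, but its log2 fold change of 0.86 had an edgeR adjusted p of 0.34. ssa-miR-2188-5p was at 21800 ± 8760 and 45700 ± 23300 CPM with overlapping groups (SD, n = 3 each; edgeR adjusted p = 0.461). The other 7, dre-miR-125b-5p, ola-miR-462_L-1R+5, ipu-miR-205_R-1, ssa-miR-99-5p, ipu-miR-92a, ssa-miR-203a-3p and ssa-miR-199a-5p, had log2 fold changes between -0.33 and 0.42, smallest edgeR adjusted p 0.594.

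**Figure D2:**
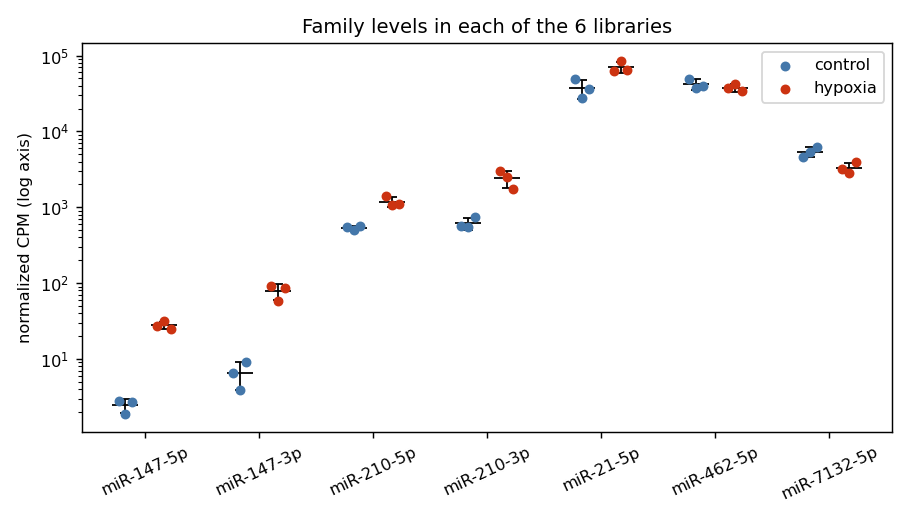
Normalized CPM (log axis) of 7 miRNA families in each control (blue) and hypoxia (red) library, with the mean as a horizontal mark and the SD as error bars (n = 3 per group). Both miR-147 arms and both miR-210 arms have every hypoxia library above every control library, whereas miR-462-5p overlaps between groups.

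Of 15 families in the list of hypoxia-induced miRNAs, 1 rose, 0 fell and 14 did not pass over all families; adjusted over the list alone, 4 passed, all higher. By camera the list stood higher than the other families (median log2 fold change 0.24, adjusted p = 0.0138), but the call was lost with an estimated correlation (adjusted p = 0.853 with an estimated correlation). By fry, which asks whether the list's families move one way and compares them with no others, the adjusted p was 0.338. The 4 were miR-210-3p, miR-210-5p, miR-21-5p at 37500 ± 10600 and 70900 ± 12100 CPM, and miR-21-3p at 66.3 ± 9.41 and 131 ± 38 CPM (SD, n = 3 each), so they came from 2 precursor types. miR-462-5p, from a cluster that responds to hypoxia in zebrafish, was at 42300 ± 6600 and 37700 ± 4480 CPM (log2 fold change -0.17, SE 0.23), and miR-181-5p at 53500 ± 6340 and 63400 ± 12700 CPM (SD, n = 3 each). Without hypoxia replicate 3, miR-21-5p passed over all families (log2 fold change 1.07, edgeR adjusted p = 0.0466, up to 0.907 over its alternatives). The list's call also ended with a mean CPM of at least 10 (adjusted p = 0.105), without hypoxia replicate 2 (0.0921, median log2 fold change 0.063), with the more abundant arm alone (0.267, median 0.066), after the GC correction (0.0581) and without sequences unmatched to the genome (0.169), in a range of 0.00155 to 0.853. Its median ran from 0.032 without scaling to 0.54 without hypoxia replicate 3.

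The remaining 13 lists tested were not called by camera (smallest adjusted p 0.643), and none of their families passed with all 6 libraries. Without hypoxia replicate 3, miR-142-5p (log2 fold change -1.60), miR-9-3p (-1.67), miR-182-5p (-1.37) and miR-25-3p (1.29) passed, with edgeR adjusted p of 0.0273, 0.0273, 0.0438 and 0.0127; each passed in that 1 of 18 alternatives, in ranges up to 0.978. HIF-targeting miRNAs, predicted or known to act on HIF transcripts, had a median log2 fold change of 0.22 over 14 families, with miR-199-5p at 0.51, miR-199-3p at 0.17 and miR-17-5p at -0.05. Epithelial families had a median of 0.09 over 8, with miR-205-5p at 0.16, miR-200-3p at 0.03 and miR-203-3p at -0.21. Another of them, miR-141-3p, came from sequences unmatched to the genome. Leukocyte families had a median of -0.36 over 8, with miR-150-5p at 0.28, miR-146-5p at -0.48 and miR-142-5p at -0.51. Vascular families had a median of 0.17 over 6, with miR-126-3p, the endothelial miRNA, at -0.23, miR-143-3p at 0.17 and miR-145-5p at 0.33. Cartilage and mesenchyme families had a median of 0.21 over 8, and miR-214-3p was at -0.02. Skeletal muscle families had a median of -0.18 over 6, with miR-133-3p at 0.01, miR-1-3p at -0.44 and miR-206-3p at -0.21. Erythroid families had a median of -0.04 over 4 with a mean of 0.03, with miR-144-3p at 0.48, miR-144-5p at -0.04 and miR-486-5p at -0.28; miR-451-5p and miR-486-5p came from sequences unmatched to the genome.

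Neural families had a median of -0.27 over 5 with a camera direction upward, with miR-128-3p at 0.28, miR-9-3p at -0.31 and miR-9-5p at 0.73. Sensory epithelium families had a median of -0.33 over 5, with miR-7-5p at -0.87, miR-182-5p at -0.85 and miR-183-5p at -0.33. In the let-7 list of 3 families the median was -0.21, with let-7-5p at 58100 ± 14100 and 58100 ± 3560 CPM (SD, n = 3 each), let-7-3p at -0.21 and miR-98-5p, which came from sequences unmatched to the genome, at -0.97. For the miR-17-92 clusters the median was -0.1 over 14 families with a camera direction upward, with miR-92-3p at 0.32, miR-25-3p at 0.88 and miR-19-3p at -0.3. In this list 98.5% of the reads of miR-106-5p were unmatched to the genome. Hox cluster families had a median of -0.18 over 3, with miR-10-5p at 0.36, miR-10-3p at -0.18 and miR-196-5p at -0.62. In the miR-34 list miR-34-5p was at 0.2 and miR-449-5p at 0.6. The liver miRNA miR-122-5p, the 1 family of its list, was at 70.9 ± 74.4 and 22.3 ± 14.1 CPM (SD, n = 3 each; edgeR adjusted p = 0.496), with 157 CPM in control replicate 3.

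Libraries also differed within groups. The trend of counts with GC content, in log2 units per 10 points of GC over 488 sequences, was -0.24, 0.11 and -0.18 in control replicates 1 to 3 and 0.22, 0.29 and -0.2 in hypoxia replicates 1 to 3. The leukocyte family miR-142-5p was at 3660, 1390 and 3080 CPM in the control libraries and 1230, 451 and 4030 CPM in the hypoxia libraries. The first principal component (45.3% of variance) placed hypoxia replicate 3 at -6.85, nearer to control replicates 1 (-7.64) and 3 (-12.57) than to hypoxia replicates 1 (11.71) and 2 (16.34).

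**Figure D3:**
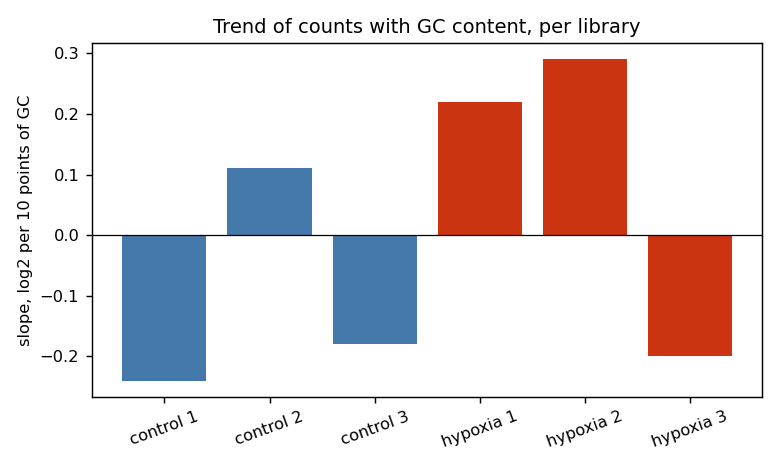
Slope of each library's log2 deviation on GC content, in log2 units per 10 points of GC, for control (blue) and hypoxia (red) libraries. Slopes run from -0.24 in control replicate 1 to 0.29 in hypoxia replicate 2, and hypoxia replicate 3 is at -0.2.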

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

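The alternatives named in the methods as chosen after seeing the data are marked as added. Both miR-147 sequences and both miR-147 families passed in every alternative in which they were followed, 21 for the sequences and 18 for the families. Their log2 fold changes were 3.02 to 3.89. Each miR-147 family had the same counts as its sequence, so the same reads were tested at both levels. By contrast, miR-210-3p passed in 17 of 18 as a family and in 17 of 21 as a sequence. Against 3 main calls, the count of sequences was 5 (4 higher, 1 lower) with no count filter, 6 with a mean CPM of at least 10, 10 with DESeq2, 5 on the authors' normalized values with a pseudocount of 1, 5 at a threshold of 0.1, 62 at an unadjusted p and 5 after the added GC correction, and 2 to 14 with a library left out. The 14 arose without hypoxia replicate 3, and without control replicate 2 the count was 5 (4 higher, 1 lower). For families the count was 2 to 22 with a library left out, 22 without hypoxia replicate 3. The number of lists called went from 1 to 0 with a mean CPM of at least 10, with an estimated correlation, with fry (which compares a list with no other families), and in the added GC correction, removal of unmatched sequences and more abundant arm alone, and was 0 to 1 with a library left out, 0 without hypoxia replicate 2. The cause was not tested, except that the stricter filter tests fewer features. The group difference in count-weighted length went from 0.0111 to -0.0238 nt without the 10 most abundant sequences, and was -0.00327 to 0.0255 with a library left out; the differences in shares were -0.0114 to 0.0232 points for named miRNAs and 1.32 to 3.89 points for the 10 most abundant sequences. With the added sum over rows these differences were 0.0236 nt, -0.000497 points and 0.5 points. With a block on the replicate number, 4 sequences, 4 families and 1 list were called. Whether equal numbers mark pairs of samples stays open. Deviations of same-numbered libraries from their group means correlated at -0.17, 0.25 and 0.36 over sequences. Control replicates 2 and 3 correlated best with their own number, and control replicate 1 with hypoxia replicate 3 (0.1). Deviations within groups of 3 depend on each other, so these values cannot decide it.

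Over 81 single sequences, families and lists, 1432 of 1568 alternative values kept direction and side of the threshold, 12 lost the call, 42 gained it and 82 changed sign. Gains at a threshold of 0.1 or an unadjusted p only set the same p against a looser cutoff. Of the other gains, 14 belong to PC-3p-3211_637. None of the 82 sign changes was past the threshold in either setting, and the cause was not tested. Without scaling, which moved the median over families from -0.17 to -0.33 and over sequences from -0.1 to -0.22, the values were -0.0009 for miR-199-3p, -0.015 for the vascular list, -0.019 for miR-143-3p and for miR-34-5p, -0.051 for miR-205-5p, -0.073 for ipu-miR-205_R-1, -0.094 for the epithelial list, -0.14 for miR-200-3p, -0.17 for let-7-5p and -0.19 for miR-133-3p. With upper quartile scaling miR-200-3p was at -0.04, let-7-5p at -0.064 and miR-133-3p at -0.10. With RLE miR-144-5p was at 0.007, the erythroid list at 0.014, miR-17-5p at 0.021 and miR-214-3p at 0.045, and with DESeq2 these families were at 0.007, 0.021 and 0.045. With no count filter miR-17-5p was at 0.0044, miR-214-3p at 0.008 and the neural list at 0.053; with a mean CPM of at least 10 let-7-5p was at -0.019 and miR-133-3p at -0.034. Without the 10 most abundant sequences miR-17-5p was at 0.017, miR-144-5p at 0.023, the erythroid list at 0.024 and miR-214-3p at 0.043. With the added authors' factors miR-133-3p was at -0.0029 and let-7-5p at -0.018. After the added GC correction miR-214-3p was at 0.00039, miR-133-3p at -0.023, ipu-miR-205_R-1 at -0.051, the skeletal muscle list at 0.055, miR-1-3p at 0.13, the erythroid list at 0.34 and miR-144-5p at 0.44. In the added removal of unmatched sequences miR-200-3p was at -0.053, let-7-5p at -0.086, miR-133-3p at -0.10 and the erythroid list at 0.13. With a library left out, values ran from -0.053 to 0.28 for ipu-miR-205_R-1, -3.1 to 0.16 for PC-3p-5453_308, -0.26 to 0.0076 for miR-462-5p, -0.23 to 0.081 for miR-17-5p, -0.067 to 0.78 for miR-144-3p, -0.29 to 0.26 for miR-144-5p, -0.49 to 0.11 for miR-486-5p, -0.093 to 0.3 for miR-200-3p, -0.44 to 0.022 for miR-203-3p, -0.059 to 0.18 for miR-133-3p, -0.33 to 0.05 for miR-206-3p, -0.53 to 0.15 for miR-126-3p, -0.04 to 0.079 for miR-214-3p, -1.67 to 0.16 for miR-9-3p, -0.15 to 0.22 for let-7-5p, -0.76 to 0.022 for miR-19-3p and -0.48 to 0.12 for miR-10-3p. For lists they ran from -0.15 to 0.18 (erythroid), -0.34 to 0.0084 (skeletal muscle), -0.38 to 0.13 (neural), -0.26 to 0.065 (miR-17-92 clusters) and -0.48 to 0.12 (Hox clusters).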

Other observations

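The tests of GC content, of cell type medians, of the authors' factors as a scaling, of the lowest value over the scalings, of the splits, of leukocyte content, of the mammalian cluster and of the hairpin arms and neighbours were chosen after the results they bear on had been seen; the edgeR fits and the other scalings were planned. Beyond the families described so far, several had an unadjusted edgeR p under 0.05 and did not pass adjustment, and they are named here after their values were seen. miR-27-3p and miR-24-3p, which share a precursor cluster in vertebrates, had log2 fold changes of 0.84 (SE 0.3) and 0.67 (SE 0.26), with edgeR adjusted p of 0.353 and 0.354; miR-23-3p of the same cluster had 0.28 (SE 0.24, edgeR adjusted p = 0.62; unadjusted p = 0.281). miR-31-5p had 0.81 (SE 0.27) and miR-725-3p 1.29 (SE 0.45), both with an edgeR adjusted p of 0.353. For miR-725-3p the hypoxia libraries were at 3780, 4920 and 1070 CPM and the control libraries at 1270, 1580 and 1160 CPM, so hypoxia replicate 3 lay below each control. In all, 26 families had an unadjusted p under 0.05, 18 higher and 8 lower, against 14 by chance. Without sequences unmatched to the genome, 195 families were tested and 16 had an unadjusted p under 0.05, 12 higher and 4 lower. With fewer families tested, the number by chance is smaller too.

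The rise of the miR-147 and miR-210 families was set against 3 technical explanations. After the GC correction the lowest log2 fold change of the 3 called families was 2.00 (miR-210-3p, SE 0.3, edgeR adjusted p = 0.000165), so a GC trend is not the whole cause. Over 5 scalings the lowest was 1.76 (miR-210-3p without scaling, edgeR adjusted p = 0.0076), while the median of all families moved only between -0.33 and -0.09, so none of these scalings is the whole cause. A shift in cell types stays open: the highest median of a marker list was 0.21 (cartilage and mesenchyme), but members went both ways in every list except liver, with 1 family, and abundant markers such as miR-150-5p (49700 CPM in control, against 616 CPM for miR-210-3p) would hide a rise of a small share of cells. A response to low oxygen, which the design names, stays open beside it and was not tested apart from it.

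A different grouping of the 6 libraries, with control replicates 1 and 3 and hypoxia replicate 3 on one side, gave 53 sequences and 27 families past the threshold, several times the 3 and 3 of hypoxia against control, which points to a structure of the samples. Counting the real grouping itself, at least as many calls arose in 2 of the 10 splits for sequences and in 2 for families. For lists this held in 7, the real grouping again included (1 list called, highest other 1). A total of 10 splits is too few for a share under 0.05. After the GC correction that grouping called 5 sequences and 5 families, and hypoxia against control called 5 and 3. Most calls of that grouping thus tracked GC content, and a GC-related difference between libraries is a candidate explanation for them. The correction removes any difference that tracks GC, whatever its cause. The drop therefore cannot tell a technical difference from one of cell content. Leukocyte content was tested by whether miR-150-5p and miR-142-5p vary together over the 6 libraries: Pearson's r was 0.19 (exact permutation p = 0.722) and Spearman's rho 0.31 (exact permutation p = 0.564), which leaves it open with 6 libraries. Without the 2 libraries farthest from the median of miR-150-5p r was 0.98 over the other 4, too few to read a relation from. The leukocyte family miR-146-5p was at 18700, 13800 and 16000 CPM on the side of hypoxia replicate 3, against 7720, 6350 and 6560 CPM. miR-142-5p and miR-142-3p followed the grouping too, whereas miR-150-5p and miR-223-3p overlapped between its sides. miR-19-3p and miR-20-5p, which are not in the leukocyte list, also followed it, so leukocyte content stays open. No label follows this grouping.

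The table holds 206 sequences unmatched to the genome, with 0.39% to 0.643% of reads per library. All 45 named sequences of a miRNA cluster known from placental mammals were in this class, against 161 of 669 other named sequences (Fisher's exact p = 1.17e-26, two-sided). Such a cluster is not expected in a fish genome, so this outcome was largely fixed by the choice of the cluster. It held 1690 of 51761 unmatched reads in control replicate 1 and 4533 of 67629 in control replicate 3. Each library held reads of this cluster, from 1493 in hypoxia replicate 1 to 4533 in control replicate 3. For these 45 sequences the reads argue against an origin in the fish genome, and reads from another organism are the candidate left. The origin of the rest of the class stays open. Relative to all reads in the rows, this cluster stood at 153, 400 and 431 CPM in control replicates 1 to 3 and at 152, 149 and 226 CPM in hypoxia replicates 1 to 3. Of the families with an unadjusted p under 0.05, 4 of the 8 lower and 2 of the 18 higher were mostly unmatched reads, whereas miR-147 and miR-210-5p had 0% and miR-210-3p 0.3%. Where the unmatched reads came from, and how they entered the libraries, was not tested.

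A hypothesis that both arms of a hairpin change together gave r = 0.59 over 78 hairpins after the GC correction (permutation p = 1e-04, the smallest that 10000 shuffled pairings can give; 2e-04 adjusted over the 2 relations tested), across miRNAs that are not independent replicates. Without miR-147 and miR-210 r was 0.18 over 76 pairs (one-sided permutation p = 0.0567), so the relation rests on these miRNAs. A hypothesis that families with precursors within 10000 bases change together gave r = 0.14 over 47 pairs after the GC correction. This lay within the shuffled pairings, whose 95th percentile was 0.25 (one-sided permutation p = 0.178, also after adjustment). The test had been written to count such a value against the hypothesis. Since a shared change with r below 0.25 would also fall there, the hypothesis is left open. Several pairs also held miR-106-5p, with 98.5% of its reads unmatched to the genome. The same families recur across pairs, and each sums all rows of a miRNA number and arm.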
